A study of Mus musculus with 29 samples.

How the data were processed

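RNA from cultured mouse primary keratinocytes with an inducible c-Fos transgene was measured on Illumina bead arrays of 25697 probes. The labels give doxycycline as 1 µg/ml in the treatment field and as 1 µg/L in the growth field, and the correct unit is not given in the sources used here. The table of signals holds intensity values that, per the file headers, the authors deposited without normalization. The same deposited table gives a detection p-value beside each signal, which steps by about 1 in 789 to 798 and was read as a comparison with the negative control beads of the array. The processed table holds the log2 values that the authors deposited after normalization, whose method is not given in the sources used here. Their slope against the log2 signal ran from 0.984 to 1.07 per array.

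The authors' values share 1 distribution within each of 4 sets of arrays and differ between sets, which was read from the values because the labels name no chip or batch. The sets hold 6, 8, 7 and 8 arrays: all 6 h arrays with 1 untreated 12 h array, the remaining 12 h arrays with the untreated 24 h arrays and 1 Dox 24 h array, 2 Dox 24 h arrays with all 48 h arrays, and all 72 h arrays. Comparisons at 6, 48 and 72 h fall within 1 set, and those at 12 and 24 h cross sets.

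Signals were corrected for background and quantile normalized with neqc of limma 3.58.1 in R 4.3.3, with an offset of 16 and the background taken from the detection p-values. Probes with a detection p below 0.01 on at least 2 of 29 arrays were kept, 11794 in all, and 13903 were removed. Of those kept 11090 carry 1 gene symbol and 704 none. A gene with several probes was counted by the probe with the highest mean, which gave 8271 genes, 2066 of them with more than 1 probe. Median signal per array ran from 54.5 to 74.5, and 33.4 to 37.8% of probes were detected, so transcripts near the background are measured poorly.

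The arrays of letter C at 72 h were averaged within treatment, leaving 27 replicates. A single limma fit held 10 group means, with 17 residual degrees of freedom, a prior of 8.32 and a prior SD of 0.158. Contrasts were Dox minus untreated at each time, their mean over 5 times, an F test on the differences of the later effects from that at 6 h, and untreated 72 h minus 6 h. Adjusted p-values are Benjamini-Hochberg over all kept probes of a contrast, with a threshold of 0.05 and no fold minimum. The letters were not used to pair samples, and whether samples with 1 letter come from 1 animal or culture is not given in the sources used here. The p-values measure only the spread between these samples.

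Genes named in the text follow a rule. Fos, Mmp10 and S100a7a are always named. For each time the 5 largest rises and 5 largest falls past the threshold with no overlap between the arrays of the treatments are named. For the mean over times it is the 10 largest each way with 1 sign at all times, for each list up to 4 members with the smallest adjusted p in that mean, for time dependence the 10 smallest p, and for untreated cultures the 10 largest each way. A gene undetected on every array of 1 group is given as a bound, against the detection limit.

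Of 32 gene lists 30 had at least 3 measured members and were tested with camera, at a preset correlation of 0.01 between genes, with Benjamini-Hochberg over lists within a contrast. Camera with the correlation estimated per list and fry were run beside it. Camera asks whether the members of a list differ more than the other genes do. Fry asks whether they differ at all, without regard to other genes, so its counts answer another question. None of 15 mitochondrial DNA-encoded genes was measured, and 1 of the sex genes was. The fit, the lists, the rule for naming genes and most alternatives were chosen before the data were examined. The array sets, the Actb probe covariate, means and contrasts without 6 h, and the immediate-early list came after.

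Alternatives covered background correction, normalization, the authors' values, the detection filter, the choice of probe, a fold minimum, the handling of the letter C arrays, array weights, replicate blocks and leaving out each replicate. The procedure was tested on simulated arrays with the measured means and spread and known changes at each time, which makes the spread between arrays independent from probe to probe. Of changes of 1 on the log2 scale it recovered 67.2% at 6 h, 68.2% at 12 h, 76.1% at 24 h, 58.2% at 48 h and 69.7% at 72 h. False calls were 5.5, 3.4, 10.3, 7.1 and 2.5% of calls.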

Results

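Gene expression was measured on 29 Illumina bead arrays of mouse primary keratinocytes, skin epithelial cells grown at 32 °C, that carry a doxycycline-inducible c-Fos transgene. Cultures given doxycycline (Dox) and untreated cultures were sampled at 6, 12, 24, 48 and 72 h. The arrays labelled Dox numbered 3 at 6, 12 and 24 h, 2 at 48 h and 4 at 72 h, and the untreated arrays 2, 2, 3, 3 and 4. At 72 h the 2 arrays of each treatment that share the letter C were averaged, which left 27 replicates in 10 groups. The median signal per array ran from 54.5 to 74.5, and 33.4 to 37.8% of the 25697 probes were detected on each array. Groups of 2 or 3 replicates limit the precision of every value. The question was which transcripts differ between cultures with and without Dox at each time. All cultures carry the transgene, so an effect of doxycycline itself cannot be told apart from an effect of c-Fos.

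The transgene's own gene, Fos, a subunit of the AP-1 transcription factor, gave a lower signal on the arrays labelled Dox. Its single probe differed by -0.76 on the log2 scale at 24 h (SE 0.16, adjusted p = 0.00535, 3 against 3 replicates), by -0.83 at 48 h (adjusted p = 0.00536, 2 against 3) and by -0.78 at 72 h (adjusted p = 0.00163, 3 against 3). At each of these 3 times all arrays labelled Dox lay below all untreated arrays. At 6 h and 12 h the differences were -0.39 and -0.32, and neither passed the test (adjusted p = 0.105 and 0.453). The position of this probe on the transgene's transcript is not given in the sources used here, so the probe does not show whether the transgene was expressed. All directions below therefore follow the labels, and "with Dox" means on the arrays labelled Dox.

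Mmp10, a secreted matrix metalloproteinase, and S100a7a, a calcium-binding protein of inflamed epidermis, were higher with Dox, while both were lower at 72 h than at 6 h in either treatment. Untreated Mmp10 went from a log2 value of 9.30 ± 0.09 (SD, n = 2) at 6 h to 5.62 ± 0.11 (SD, n = 3) at 72 h, while with Dox it went from 9.65 ± 0.12 (SD, n = 3) to 7.57 ± 0.22 (SD, n = 3). The Mmp10 difference was 1.05 at 12 h, 2.02 at 24 h, 2.08 at 48 h and 1.95 at 72 h, the last a 3.86-fold higher level with Dox (adjusted p = 4.67e-10). At 6 h it was 0.35 (SE 0.16) and did not pass the test (adjusted p = 0.118). The S100a7a difference was 0.55 at 6 h, 1.01 at 24 h, 1.21 at 48 h and 1.32 at 72 h, all past the threshold, and 0.41 at 12 h (adjusted p = 0.102). Both genes are among those the study is known to have followed up, so their higher level is not independent evidence. At 6 h the S100a7a call ended without untreated replicate 2 (0.42, adjusted p = 0.0699) and with a covariate for the Actb probe difference given for 72 h (0.26, adjusted p = 0.682).

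**Figure D1:**
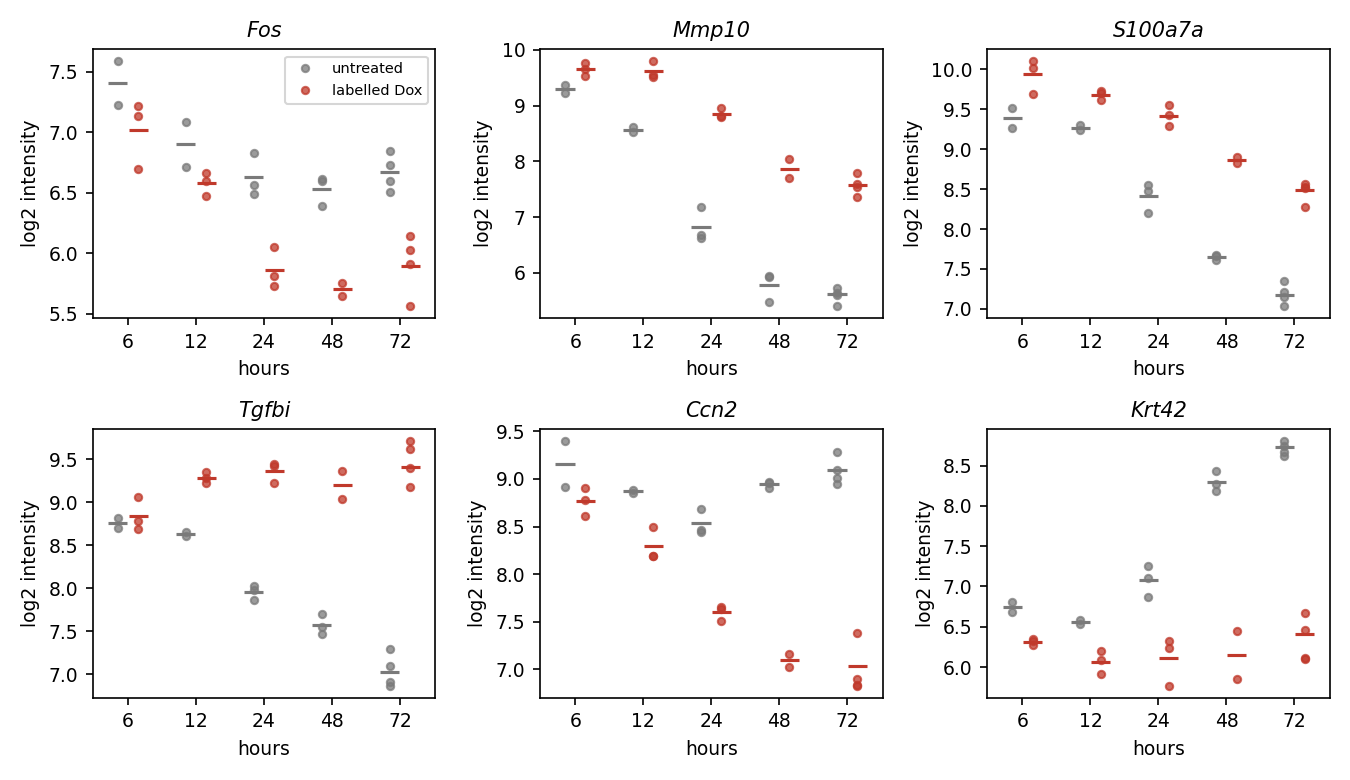
Normalised log2 signal of 6 genes against hours, 1 point per array, untreated cultures and arrays labelled Dox side by side; horizontal bars mark the group means. Fos lies lower and Mmp10 and S100a7a lie higher on the arrays labelled Dox at 24, 48 and 72 h.

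At 72 h the largest falls with Dox were in Prmt1, an arginine methyltransferase (-2.50, SE 0.31), Igfbp2, an insulin-like growth factor binding protein, Krt42, a type I keratin (-2.32, SE 0.15), Ccn2, the matricellular connective tissue growth factor (-2.06, SE 0.14), and Fhl1, a LIM-domain protein (-2.03, SE 0.11). Igfbp2 was not detected on any array labelled Dox, against 6.86 ± 0.14 (SD, n = 3) in untreated cultures, so on that probe it was at least 4.29-fold lower, and its other probe differed by -1.16. The largest rises were in Tgfbi, an extracellular matrix protein (2.38, SE 0.12, and 1.55 on its other probe), Taf15, an RNA-binding protein undetected in untreated cultures and at least 3.80-fold higher with Dox, Mmp10, Mgst3, a microsomal glutathione transferase (1.53, SE 0.11), and Stmn2, a regulator of microtubules (1.48, SE 0.17). Stmn2 was detected on 2 of 4 untreated arrays, so the size of its difference is uncertain. Adjusted p ran from 2.33e-14 for Igfbp2 to 8.19e-06 for Taf15. For each gene all arrays labelled Dox lay on 1 side of all untreated arrays, which the rule for naming genes requires.

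Among the gene lists, the basal keratinocyte genes were higher at 72 h. Of 13 measured, 3 rose, 0 fell and 10 did not pass the test (adjusted over the list alone, 6 and 0). The laminin receptor subunit Itga6 rose by 0.89, and so did, named after their values were seen, the hemidesmosomal collagen Col17a1 by 0.73 and the basal transcription factor Trp63 by 0.56. The list's camera adjusted p was 8.23e-04, and the adjusted p was 0.0108 with an estimated correlation. Chemokines were lower, with 0 of 10 rising and 3 falling, also 0 and 4 adjusted over the list alone. Cxcl1, a neutrophil attractant, differed by -1.34, Cxcl12 by -1.35 on the brightest of its 3 probes (-0.30 and -0.26 on the others, neither past the threshold), and Cxcl16 by -0.39. The camera adjusted p was 0.00216, and the adjusted p was 0.0196 with an estimated correlation. The arrays also differed at 72 h in a pair of probes of Actb, beta-actin, whose log2 difference was -2.41 to -1.71 on untreated arrays and -3.71 to -3.10 with Dox. With that difference as a covariate, chosen after the data were seen, the basal keratinocyte and chemokine lists were still called (adjusted p = 0.00133 and 0.00291).

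The test called 6 further lists at 72 h. Antimicrobial genes were lower: 4 of 13 fell, Defb14, Slpi and Defb6 between -0.58 and -0.47 and Chil1, which was undetected with Dox, and 0 rose (adjusted p = 0.0437, and adjusted p = 0.131 with an estimated correlation). Of 6 measured genes of the EGF receptor ligand list, which also holds receptors and Errfi1, 3 fell and 0 rose: the ligand Epgn at -0.95, the receptor Egfr at -0.39 (-0.12, -0.34 and -0.26 on its other probes, none past the threshold) and, named after its value was seen, the ligand Btc at -0.51 (adjusted p = 0.0437, and adjusted p = 0.105 with an estimated correlation). In the mesenchymal shift list 3 of 15 fell and 1 rose: the contractile actin Acta2 (-1.71, and from -1.72 to -0.95 on 3 other probes), the mucin-type glycoprotein Pdpn (-1.47) and the matrix protein Tnc (-1.21, and from -0.94 to -0.13 on 4 other probes) were lower while Igfbp3 was higher (1.18). That list's adjusted p was 0.0437, with an adjusted p of 0.172 with an estimated correlation, 0.0569 with the set as a block and 0.0642 with cyclic loess. Mitosis genes were lower, with 2 of 17 falling and 0 rising (adjusted p = 0.0158, and adjusted p = 0.273 with an estimated correlation). The integrated stress response list (1 of 29 rising, 1 falling) and the hypoxia and glycolysis list (1 of 19 rising, 1 falling) were called higher, both at adjusted p = 0.0437, with adjusted p = 0.181 and 0.105 with an estimated correlation. Adjusted over each list alone, the counts that rose and fell were 0 and 5 for antimicrobial genes, 0 and 3 for EGF receptor ligands, 1 and 4 for the mesenchymal shift, 0 and 3 for mitosis, 2 and 1 for the stress response and 2 and 1 for hypoxia and glycolysis. With the Actb covariate all 6 calls ended, at adjusted p = 0.0602 for antimicrobial and for mitosis genes, 0.0652 for EGF receptor ligands, 0.0741 for hypoxia and glycolysis, 0.0816 for the mesenchymal shift and 0.151 for the stress response. Of the 8 lists 4 were called with median scaling and 4 on the authors' values.

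In all, 517 of 8271 genes passed the threshold at 72 h, 241 higher and 276 lower with Dox, and 61 of them differed at least 2-fold. All 72 h arrays belong to 1 of the 4 array sets described with the processing. The count was 342 without Dox replicate 2 and 342 on the authors' values.

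**Figure D2:**
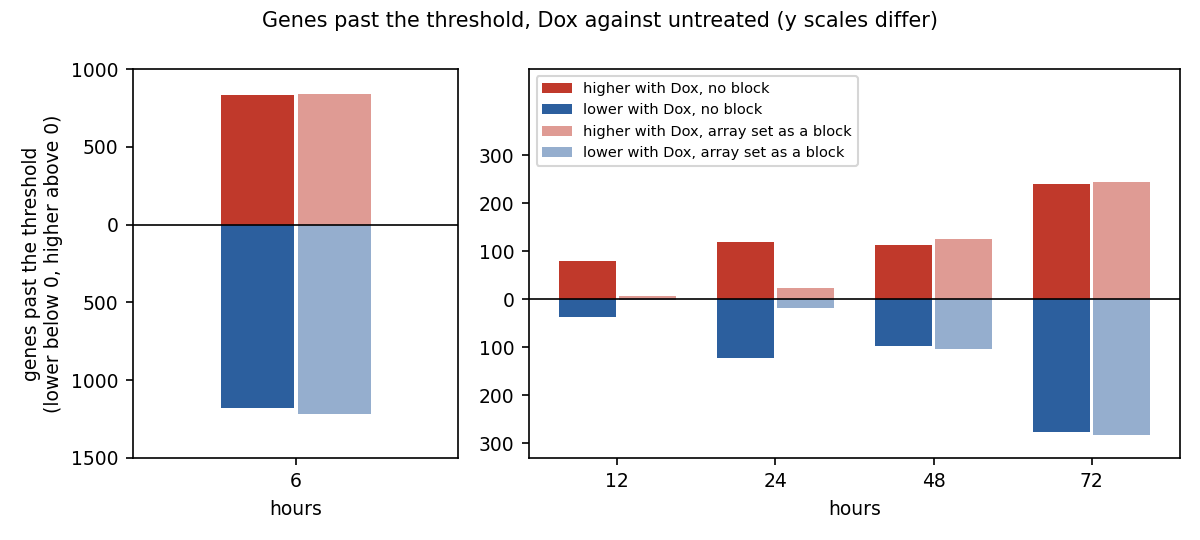
Number of genes past adjusted p 0.05 at each time, higher and lower with Dox, in hours; pale bars hold the array set as a block, and the panels for 6 h and for the later times have different y scales. Without the block the plot shows 2013 genes at 6 h, 116 at 12 h, 241 at 24 h, 212 at 48 h and 517 at 72 h.

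At 48 h the list of small proline-rich proteins, precursors of the cornified envelope, was called higher. Of 11 measured, 4 rose, 0 fell and 7 did not pass the test (adjusted over the list alone, 6 and 0): Sprr2e by 0.98, Sprr2k by 0.74, Sprr2d by 0.64 and, named after its value was seen, Sprr2f by 0.73. The list's camera adjusted p was 6.39e-07, and the adjusted p was 0.0199 with an estimated correlation. S100 genes were higher (2 of 13 rose, 0 fell, the same adjusted over the list alone; S100a7a 1.21 and S100a16 0.71), with adjusted p = 0.00631, and adjusted p = 0.157 with an estimated correlation. Mitosis and DNA replication genes had medians of -0.25 over 17 and -0.18 over 26 measured genes, with no single gene of either list past the threshold over all probes and 2 and 3 lower over the list alone. Their adjusted p values were 9.51e-04 and 0.00306, and both had adjusted p = 0.157 with an estimated correlation. Basal keratinocyte genes had a median of 0.17 over 13, with 0 past the threshold over all probes and 3 higher over the list alone (adjusted p = 0.0495, and adjusted p = 0.157 with an estimated correlation). That call also ended with the array set as a block (adjusted p = 0.0563) and with a block for the letter (adjusted p = 0.0677).

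The single genes that moved most at 48 h were mainly those of 72 h. Krt42 (-2.15, SE 0.17), Ccn2 (-1.85), Fhl1 (-1.78), the metalloproteinase inhibitor Timp3 (-1.51 on 1 probe and -0.09 on the other) and the vasoactive peptide Edn2 (-1.36) were lowest. Mmp10, Tgfbi (1.62 on 1 probe and 0.96 on the other), Stmn2 (1.44), the guidance molecule Sema5a (1.32) and Mgst3 (1.23) were highest, with adjusted p from 3.75e-10 for Fhl1 to 2.60e-05 for Stmn2. Stmn2 was detected on 1 of 3 untreated arrays at 48 h, so the size of its difference is uncertain. A total of 212 genes passed, 114 higher and 98 lower, of which 159 also passed at 72 h, all in the same direction, where 13.3 would be shared by chance. Across genes, which are not independent replicates, the differences at 48 h and 72 h correlated at Pearson's r = 0.52 and Spearman's rho = 0.35. The count was 128 without Dox replicate 1, 114 without Dox replicate 2 and 30 on the authors' values, where Timp3 did not pass the test (-0.42, adjusted p = 0.0648).

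At 24 h the rise of Mmp10 and Tgfbi (1.41, SE 0.12) and the fall of Fhl1 (-1.12), the scaffold protein Akap12 (-1.08), the adhesion protein Flrt2 (-1.05), Edn2 (-1.04) and the cytochrome Cyp2b10 (-1.03 on 1 probe and 0.03 on the other) were already past the threshold. The complement regulator Cr1l was higher by 1.07 (SE 0.14, and 0.70 on its other probe). The stress enzyme Hmox1 (1.18, SE 0.22) and the chaperone Pdia3 (1.20) were also higher. Hmox1 was detected on 2 of 3 untreated arrays, so the size of its difference is uncertain. With the array set as a block each 24 h difference equals that of 1 Dox array from the 3 untreated arrays, so the block is not an independent test of these genes. On that 1 array Mmp10 was at 2.13, Tgfbi at 1.27, Cr1l at 1.24, Fhl1 at -0.95, Akap12 at -1.01, Flrt2 at -0.97, Edn2 at -1.16 and Cyp2b10 at -1.26. Hmox1 (1.14, SE 0.32, adjusted p = 0.167), Pdia3 (1.10, adjusted p = 0.277) and Fos (-0.82, adjusted p = 0.125) did not pass there, at about the same size and with a wider error. Of 8 AP-1 genes 1 rose and 4 fell at 24 h: Fosl1 was at 0.45, Fos at -0.76, Atf3 at -0.67, Junb at -0.55 and, named after its value was seen, Jdp2 at -0.62. Their camera adjusted p was 0.0675, and the adjusted p was 0.237 with an estimated correlation. With the block the list's adjusted p was 0.0417 and 1 of the 8 passed, Atf3 (-0.80), values that rest on 1 Dox array.

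At 24 h 241 genes passed, 119 higher and 122 lower, but the arrays labelled Dox were split between array sets and the untreated arrays were not. With the set as a block 40 genes passed, 38 of them shared with the 241, and a fit of the 1 set that holds both treatments gave 37. Both are the same comparison of 1 Dox array with 3 untreated arrays. The Actb probe difference was 0.91 on untreated replicate 1 at 24 h and -4.12 and -3.39 on the other 2. The small proline-rich list was called higher at 24 h (median 0.23, 1 of 11 past the threshold and 4 adjusted over the list alone, camera adjusted p = 0.00893). Its adjusted p was 0.237 with an estimated correlation, 0.0636 with median scaling and 0.429 on the 1 Dox array of the block. The count at 24 h was 115, 132, 111 and 115 without untreated replicate 1, untreated replicate 3, Dox replicate 2 and Dox replicate 3.

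At 12 h Mmp10 was higher by 1.05 (SE 0.16, adjusted p = 0.00199), and by 1.10 with the array set as a block (adjusted p = 0.0386), which at 12 h compares the 3 Dox arrays with 1 untreated array. With the Actb covariate it was 0.89 (SE 0.20) and did not pass (adjusted p = 0.203). The elongation factor Eef2 (2.10), the trafficking GTPase Rab1b (1.68), the helicase Ddx5 (1.52), the RNA-binding protein Hnrnpk (1.43 on 1 probe and 0.02 on the other) and the desmosomal Dsc3 (1.38) were higher. Pcbp1, another RNA-binding protein (-1.16), the death receptor Tnfrsf10b (-0.92 on 1 of 4 probes), Prrc2a (-0.89), the deacetylase Hdac4 (-0.85) and the adhesion molecule Mcam (-0.83 on 1 of 3 probes) were lower. Ddx5 was detected on 1 of 2 untreated arrays and Mcam on 1 of 3 arrays labelled Dox, so the sizes of their differences are uncertain. Against the 1 untreated array that the block keeps, Eef2 was at 0.72, Rab1b at 1.04, Ddx5 at 0.66, Hnrnpk at 0.87, Dsc3 at 0.97, Pcbp1 at -1.35, Tnfrsf10b at -0.82, Prrc2a at -0.77, Hdac4 at -0.79 and Mcam at -0.63. Their adjusted p ran from 0.073 for Pcbp1 to 0.635 for Eef2, with a median SE over all genes of 0.180 against 0.145. The integrated stress response list was called higher (median 0.13 over 29 genes, 1 past the threshold, Atf5 at 0.91, and 2 over the list alone; camera adjusted p = 0.0185, adjusted p = 0.165 with an estimated correlation, 0.00874 with the block and 0.328 with the Actb covariate). With the block, on 1 untreated array, the mitosis and DNA replication lists were called lower (medians -0.20 and -0.15, both adjusted p = 0.005). Without it both had adjusted p = 0.056, and adjusted p = 0.576 and 0.463 with an estimated correlation.

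At 12 h 116 genes passed, 79 higher and 37 lower. With the set as a block 9 passed, 7 of them shared with the 116, and a fit of that set alone gave 6. Both are the same comparison of 3 Dox arrays with 1 untreated array, the one that is also left without untreated replicate 1, where the count was 8. With the Actb covariate 1 gene passed. The count was 52 without Dox replicate 2 and 58 without Dox replicate 3.

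At 6 h the largest rises with Dox were in the splicing factor Srsf5, by 3.45 (SE 0.19), the elongation factor Eef2 by 3.44 (SE 0.46), Hnrnpk by 3.12, the spliceosomal Snrpd3 by 2.58 and the heparan sulphate proteoglycan Sdc1 by 2.58. Asap2 (-1.57), the ephrin receptor Epha1, the co-chaperone Dnajc7 (-1.49), the cell-cycle repressor E2f4 (-1.37) and the dynamin Dnm2 were lower. Epha1 and Dnm2 were not detected with Dox and were at least 2.15-fold and 1.80-fold lower. Hnrnpk was detected on 1 of 2 untreated arrays, so the size of its difference is uncertain. Probes of 1 gene often disagreed: the other probe gave 0.65 for Hnrnpk, 0.46 for Sdc1 and 0.19 for Asap2, and the other probes of Epha1 gave 0.06 and 0.07. The second Srsf5 probe gave 2.37, and the other probes of Eef2 gave 3.27 and 3.44. Over the 628 genes called at 6 h with at least 2 probes, 64.5% of second probes had the same sign (r = 0.385), against 89.8% of 157 genes at 72 h (r = 0.831).

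The untreated arrays at 6 h stood apart over all kept probes and in those of an abundant transcript. On the second principal component, an axis of variation between arrays that held 12.5% of the variance, they lay at -29.0 and -31.1. The 6 h arrays with Dox lay between 10.2 and 13.7 there, the untreated 12 h arrays at -3.92 and 2.22, and all other arrays between -10.9 and 14.5. This position does not tell an array property from an effect of treatment. Of the 5 probes of Actb 3 were lower with Dox at 6 h, 1 by a difference of -5.88 and 2, undetected with Dox, at least 17.4-fold and 10.7-fold, and the other 2 were higher (2.17 and 0.72). The difference between a pair of these probes was 3.96 and 4.59 on the untreated arrays at 6 h, between -4.03 and -3.44 on the 6 h arrays with Dox, and 1.63 and 1.10 on the untreated arrays at 12 h. With that difference as the covariate 168 genes passed at 6 h, while the median SE went from 0.145 to 0.293 and the median size of the 2013 called differences from 0.54 to 0.48. Srsf5 (2.64), Hnrnpk (1.53), Snrpd3 (2.08), Sdc1 (1.78) and Dnajc7 (-2.34) still passed, and Eef2 (1.20, adjusted p = 0.509), Asap2 (-0.21), E2f4 (-0.89, adjusted p = 0.165), Epha1 (adjusted p = 0.186) and Dnm2 (adjusted p = 0.154) did not. The slope of the covariate rests on differences within groups, the widest from -4.12 to 0.91 on untreated arrays at 24 h. The gap between treatments at 6 h was wider, so passing or not does not sort treatment effects from array properties.

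**Figure D3:**
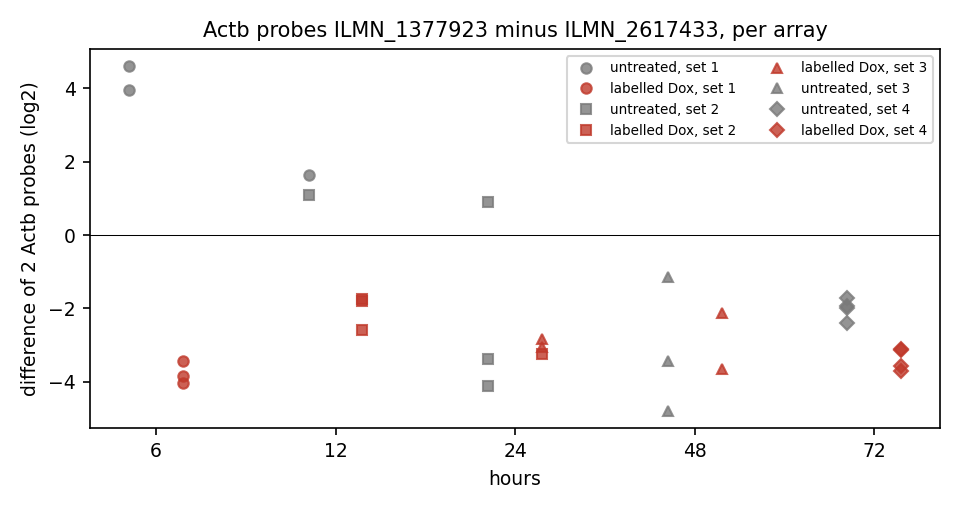
Log2 difference between a pair of Actb probes on each of the 29 arrays against hours, with the array set as the marker shape and treatment as the colour. The untreated arrays at 6 h lie at 3.96 and 4.59 and the arrays labelled Dox at 6 h between -4.03 and -3.44.

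At 6 h 2013 genes passed, 834 higher and 1179 lower, with 222 at least 2-fold apart. The split between directions depended on the scaling, from 28.9% higher with median scaling to 53.2% on the authors' values, which called 532 genes. Without untreated replicate 2 the count was 1308. By camera 0 of 30 lists were called at 6 h, with 2 at an unadjusted p under 0.05 and 8 called by fry. The S100 list came nearest, with 5 of 13 higher, 1 lower, the same adjusted over the list alone, and adjusted p = 0.08. Across genes the differences at 6 h correlated with those at 12 h at r = 0.35, at 24 h at r = 0.15, at 48 h at r = 0.03 and at 72 h at r = 0.14. At both 6 h and 12 h 48 genes were higher and 17 lower, where 7.97 and 5.27 would be shared by chance, and 4 were opposite. The chance values take the comparisons as independent. The Actb probe difference was higher on untreated than on Dox arrays at both times. The overlap therefore does not tell a shared array property from a shared effect of Dox.

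Averaged over the 5 times, Dox cultures held more Mmp10 (1.49, SE 0.07), Cr1l (1.26), Tgfbi (1.23), the growth factor binding protein Igfbp3 (1.23), the caveolar protein Cav2 (1.06), the epidermal lipase Lipn (0.99), Psg18 (0.95), the water channel Aqp3 (0.91), S100a7a (0.90) and Sdc1 (0.90 on 1 probe and 0.26 on the other). They held less Krt42 (-1.27), Ccn2 (-1.16), Fhl1 (-1.01), Edn2 (-0.98), Timp3 (-0.85), the ectonucleotidase Nt5e (-0.84), Ankk1 (-0.83), Igfbp2 (-0.82), Snai3 (-0.81) and the kinase Dapk2 (-0.79). Other probes gave -0.14 for Timp3, -0.36 for Nt5e, -0.33 for Igfbp2 and -0.24 for Dapk2. The means of Cav2 and Igfbp2 include groups in which these were undetected, so they are not fold changes of a measured level. All 20 were chosen to have 1 sign at every time, and had SE between 0.05 and 0.12 and adjusted p of at most 2.69e-06. Over the mean of 48 h and 72 h alone, Aqp3 (0.36, adjusted p = 0.296) and Sdc1 (0.34, adjusted p = 0.103) did not pass.

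S100 genes were higher in the mean over times, with 4 of 13 rising, 0 falling and 9 not past the test (5 and 1 adjusted over the list alone): S100a7a, S100a16 (0.46), S100a14 (0.29) and S100a3 (0.27). The list's camera adjusted p was 0.00565, and the adjusted p was 0.163 with an estimated correlation. The study is known to have followed up S100a7a, so this list is not independent evidence of its direction. Small proline-rich genes were higher, with 5 of 11 rising and 0 falling (5 and 0 over the list alone, with Sprr2k at 0.45, Sprr2e at 0.40, Sprr2d at 0.19 and Sprr1b at 0.18), with adjusted p = 0.00565, and adjusted p = 0.163 with an estimated correlation. This mean rests mainly on 24 h and 48 h: the list's median was 0.02 at 6 h, 0.03 at 12 h, 0.23 at 24 h, 0.47 at 48 h and 0.07 at 72 h. At 72 h the list was not called (camera adjusted p = 0.244). Of 13 basal keratinocyte genes 5 rose, among them Sdc1, Itga6 (0.51) and the hyaluronan receptor Cd44 (0.52, with 2 of its 6 probes at -0.03 and -0.01), and 1 fell, the cadherin Cdh3 (-0.34), with 5 and 2 over the list alone. That list was called higher, with adjusted p = 0.00641, and adjusted p = 0.086 with an estimated correlation. Of 29 integrated stress response genes 9 rose and 2 fell, the same over the list alone: the transcription factors Atf4 (0.67) and Atf5 (0.41), the serine synthesis enzyme Phgdh (0.78) and Chac1 (0.29) were among those that rose. The stress response list had adjusted p = 0.00641, and adjusted p = 0.163 with an estimated correlation, 0.0527 with median scaling and 0.404 with the Actb covariate. With that covariate Atf5 (0.29, adjusted p = 0.264), Phgdh (0.28), Chac1 (0.31, SE 0.09 against 0.05, adjusted p = 0.0792), Cd44 (0.27, adjusted p = 0.259), Cdh3 (-0.23), S100a3 (0.21), Sprr2e (0.31), Sprr2d (0.18) and Sprr1b (0.17) did not pass. Over 48 h and 72 h neither did Atf4 (0.21), Atf5 (0.04, adjusted p = 0.922), Phgdh (0.37), Cd44 (0.22, adjusted p = 0.352), Cdh3 (-0.07), S100a14 (0.08) and Sprr1b (0.22).

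Of 17 mitosis genes 7 fell and 0 rose (9 and 0 over the list alone): Kif22 (-0.32), Cdc20 (-0.28, and from -0.40 to -0.10 on 3 other probes), Cdca3 (-0.26) and Aurka (-0.26). The list was called lower, with adjusted p = 0.00641, and adjusted p = 0.246 with an estimated correlation and 0.135 with the Actb covariate. Of 26 DNA replication genes 6 fell, such as Tk1 (-0.35, and 0.02 and -0.34 on other probes), Rrm2 (-0.30), Rrm1 (-0.25) and Mcm10 (-0.24), and 1 rose, with 10 and 1 over the list alone. That list was called lower, with adjusted p = 0.0124, and adjusted p = 0.222 with an estimated correlation and 0.14 with the Actb covariate. With the Actb covariate Kif22 (-0.32) still passed, and Cdc20 (-0.19, adjusted p = 0.298), Cdca3 (-0.27, SE 0.10 against 0.06, adjusted p = 0.194), Aurka (-0.14, adjusted p = 0.4), Tk1 (-0.30), Rrm2 (-0.14), Rrm1 (-0.05) and Mcm10 (-0.24, SE 0.10 against 0.06, adjusted p = 0.244) did not. All 6 lists called in the mean were called with the array set as a block, 3 with the Actb covariate (S100, small proline-rich and basal keratinocyte genes) and 0 with camera's estimated correlation, while fry called 17 of 30.

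**Figure D4:**
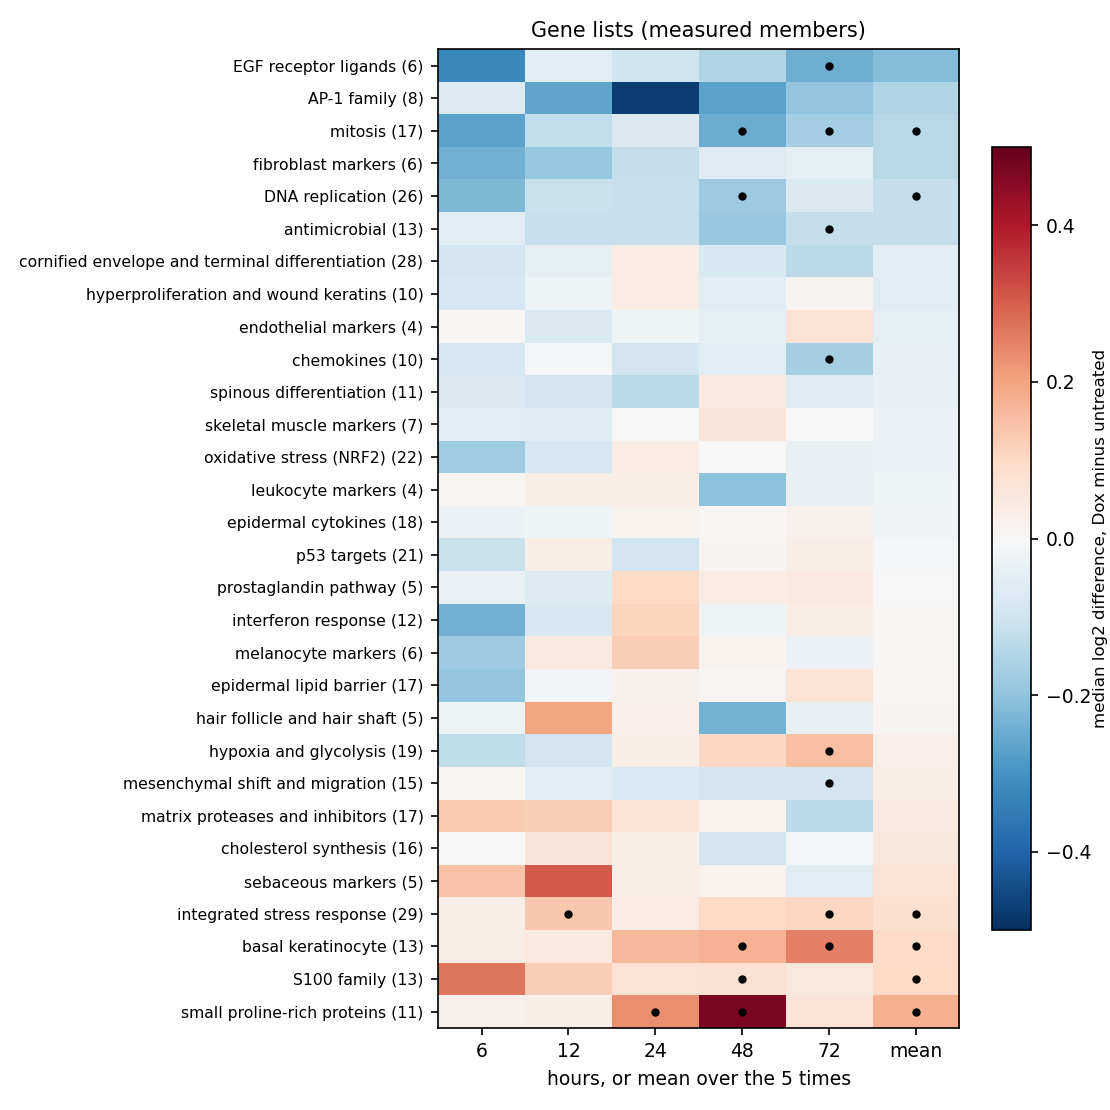
Median log2 difference, Dox minus untreated, of the measured members of each of 30 gene lists, by time in hours and for the mean over times; the number measured stands beside each name, and a dot marks a camera adjusted p under 0.05 with the preset correlation. Dots appear for 0 lists at 6 h, 1 at 12 h, 1 at 24 h, 5 at 48 h, 8 at 72 h and 6 in the mean.

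In the mean over times 1624 genes passed, 711 higher and 913 lower, and 744 of these had 1 sign at all 5 times. Of the 1624, 9 differed at least 2-fold. With the Actb probe difference as a covariate 256 genes passed. The 1624 differences then had a median size of 0.21 against 0.25 and the same sign in 96.3%, while the median SE over all genes went from 0.0622 to 0.106. Over 12 to 72 h the count was 908, and 602 with the array set as a block.

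The difference between Dox and untreated cultures depended on time for 1220 genes, tested on the 4 differences from 6 h. Igfbp2 was undetected in both treatments at 6 h and at least 4.29-fold lower with Dox at 72 h. Fhl1 moved from -0.07 at 6 h to -2.03 at 72 h, Ankk1 from -0.29 to -1.82, Tgfbi from 0.09 to 2.38, Mgst3 from -0.19 to 1.53 and Sema5a from -0.50 to 1.28. The apoptosis gene Pmaip1 moved from 1.08 to -1.49. Srsf5 went from 3.45 at 6 h to -0.43 at 72 h, Syngr2 from 1.91 to -0.02 and Ivns1abp from 1.56 to -0.16. Adjusted p ran from 2.41e-10 for Igfbp2 to 2.92e-07 for Syngr2 and Ivns1abp. Among 12, 24, 48 and 72 h alone 151 genes passed, and Sema5a (adjusted p = 0.0639), Syngr2 (0.894) and Ivns1abp (0.223) did not. The count was 811 without untreated 6 h replicate 2.

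Of 28 cornified envelope genes in untreated cultures from 6 h to 72 h, 20 fell, 0 rose and 8 did not pass the test (21 and 0 adjusted over the list alone), such as the kallikreins Klk5 (-2.84) and Klk6 (-2.79), with adjusted p = 5.61e-09, and adjusted p = 0.00366 with an estimated correlation. Of 17 epidermal lipid barrier genes 12 fell and 0 rose (the same over the list alone), with the lipoxygenase Alox12b at -2.89. Of 17 mitosis genes 16 rose and 0 fell (the same over the list alone), with Cdc20 at 2.17, adjusted p = 7.45e-13, and adjusted p = 0.00366 with an estimated correlation. Mmp13 (-3.80), Mmp10 (-3.68), the histone H1f2 (-3.15), Asap2 (-2.86 on 1 probe and 0.11 on the other) and the transcription factor Ovol1 (-2.85) were lower. Hs3st1 and Itgb7 were undetected at 72 h and at least 10.4-fold and 5.16-fold lower.

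The largest rises in untreated cultures were in Eef2 (4.49), Ms4a10 (4.09), Srsf5 (3.82), Hnrnpk (3.71 on 1 probe and 0.54 on the other), Hnrnpa2b1 (3.43 and -0.29), Snrpd3 (3.41), Phgdh (3.26), Pdia3 (3.05) and Rbbp7 (2.96), and Ddx5 was at least 5.96-fold higher. Of these, Eef2, Srsf5, Hnrnpk and Snrpd3 are also among the genes that differed most between the treatments at 6 h. Both comparisons subtract the same untreated 6 h arrays, so low values there would give this overlap by themselves. Hnrnpk was detected on 1 of those 2 arrays, so the size of its rise is uncertain. In total 3682 genes passed, 1625 higher and 2057 lower, 791 of them at least 2-fold apart. With median scaling the median of all genes moved by -0.106. The 6 h and 72 h arrays lie in different array sets, so time and set cannot be told apart here. Untreated 48 h against 6 h gave 3456 genes, and 635 with the set as a block, where lone arrays at 12 h and 24 h link the sets. There Eef2 (1.51 against 4.30, adjusted p = 0.215), Pdia3 (1.20 against 2.03, adjusted p = 0.302) and Ddx5 (adjusted p = 0.129) did not pass.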

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

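The tests on Actb probes, probe pairs, array sets and probes without a symbol were chosen after the results were seen, and the test of a persisting early response was written before its result.

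The difference between Dox and untreated cultures depended on time, by the F test, for 1220 genes. The 10 smallest adjusted p values were 2.41e-10 for Igfbp2, 2.37e-09 for Srsf5, 3.08e-09 for Fhl1, 5.75e-08 for Tgfbi, 9.18e-08 for Mgst3, 1.38e-07 for Pmaip1, 1.48e-07 for Ankk1, 1.92e-07 for Sema5a, and 2.92e-07 for Syngr2 and for Ivns1abp. These stand out as differences between times in the gap between arrays labelled Dox and untreated arrays. The F test was built on differences from 6 h, so a property of the untreated 6 h arrays would also enter it. It therefore cannot tell such a property from a change in the effect of Dox. Among the later times alone 7 of these 10 genes kept the call, and 3 did not: Sema5a, Syngr2 and Ivns1abp. No group held 4 replicates, so no single replicate was tested as lying far from its group.

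The largest count of calls was at 6 h, the earliest time, and this pattern was weighed. A difference between array sets is argued against, because the 6 h arrays of both treatments lie in 1 set. Persistence of the 6 h differences as a whole is argued against, since across genes they correlated with the mean 48 h and 72 h effect at r = 0.098. That value takes in all genes, most of them not called, and even 48 h and 72 h correlated at only 0.52. Of genes called at both 6 h and 72 h, 52 were higher and 69 lower at both times. By chance 24.3 and 39.3 would be shared, taking the comparisons as independent, and 52 were opposite. Whether a part of the 6 h response persists therefore stays open. Differences tied to the probe rather than the transcript may account for part: over genes called at 6 h the 2 brightest probes correlated at r = 0.385, against 0.831 at 72 h. A property of the untreated 6 h RNA or its labelling, read from opposed Actb probes, cannot be told apart from treatment, because r was 0.345 with a sign of prediction set after it was seen, and an early effect of Dox stays open too.

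Probes without a gene symbol took no part in the counts of genes. Of 704 that were kept, 135 passed in the mean over times, 68 higher and 67 lower. The largest was ILMN_2660233, chosen after its value was seen, at 1.29, with 1.27, 1.34, 1.22, 1.26 and 1.35 from 6 h to 72 h.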

How the results depend on the processing

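The array set, the Actb probe covariate, the contrasts and means without 6 h, the authors' values with a set block and the extra list scalings were tests chosen after the data were seen; the others were set beforehand.

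Among the alternatives set beforehand, 3132 of 3315 values of named genes kept their direction and side of the threshold, 160 lost the call, 6 gained it and 0 reversed a called direction. Leaving out replicates kept 4202 of 4349, and the added alternatives 828 of 1104. Most named genes were chosen by size or p on these same arrays, so these shares do not hold for genes at large. A gene named in the mean is also counted again for each replicate left out. For lists, 815 of 930 values set beforehand were kept, most of them lists not called in the main fit. Of 31 list calls in the main fit, 22 ended with an estimated correlation. The correlation of the 48 h and 72 h effects stayed between 0.477 and 0.623.

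With at least 2-fold required, the counts were 222 at 6 h, 16 at 12 h, 15 at 24 h, 30 at 48 h, 61 at 72 h, 9 in the mean and 791 in untreated cultures, since fewer genes can pass, and Fos (-0.616 in the mean) was not called. Counting every probe gave 191 at 12 h, and median scaling 387 at 24 h. The authors' values gave 532 at 6 h, 30 at 48 h and 342 at 72 h, and with a set block 73 at 12 h and 84 at 24 h. Fits of only the arrays of that time gave 16 at 12 h, 89 at 24 h and 61 at 48 h, with fewer arrays to estimate the spread. A block of replicates that share only a letter within a time gave 68 at 12 h. The cause was not tested for the other counts.

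With the array set as a block 9 genes passed at 12 h and 40 at 24 h, and among arrays of 1 set 6 and 37; at each time both rest on 1 lone array (untreated at 12 h, Dox at 24 h) and are 1 comparison, and the median SE at 12 h rose from 0.145 to 0.180. With the Actb covariate the counts were 168 at 6 h, 1 at 12 h, 256 in the mean, 358 for time dependence and 1745 in untreated cultures. At 6 h the median SE went from 0.145 to 0.293 and the median size of the 2013 called differences from 0.542 to 0.479, and the differences correlated at 0.665 across genes between the fits; how many calls ended through the wider error was not tested. Means over 12 to 72 h gave 908 genes, 602 with the set block, and over 48 and 72 h 701. Untreated 72 h against 12 h gave 2454, and untreated 48 h against 6 h with the set block 635. Time dependence among 12 to 72 h gave 151.

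The gene lists called in the mean numbered 0 of 30 with camera's estimated correlation, 17 with fry, 3 with the Actb covariate and 11 over 48 and 72 h, against 6; of the 11, only basal keratinocytes (adjusted p = 0.0199) kept the call with an estimated correlation, the others being at 0.0607 to 0.241. Directions reversed for Thy1 (0.084 with the Actb covariate), Cidea (-0.397) and Tnni2 (0.434), the last 2 over 48 and 72 h; the cause was not tested.

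Without each replicate in turn, counts ran from 1308 to 1811 at 6 h, 8 to 157 at 12 h, 111 to 270 at 24 h, 114 to 202 at 48 h, 342 to 411 at 72 h, 1351 to 1627 in the mean, 811 to 1306 for time dependence and 2950 to 3371 in untreated cultures. Beyond 1.5 times were untreated 6 h replicate 2 (1308; time dependence 811), at 12 h untreated replicate 1 (8) and Dox 2 and 3 (52, 58), at 24 h untreated 1 and 3 and Dox 2 and 3 (115, 132, 111, 115), at 48 h Dox 1 and 2 (128, 114) and at 72 h Dox 2 (342). A lone array left in a group is assumed to vary like the other groups.

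A chip block was not run because the labels name no chip. The authors' values were not compared across sets without a block, and a set block could not be fitted for untreated 72 h against 6 h. With 33.4 to 37.8% of probes detected, signal over background limits the weakest transcripts.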

Other observations

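The tests of exchanged labels and of immediate-early genes were chosen after the results were seen, and the tests of array sets at 24 h, of lag, of regrouped replicates and of untreated 72 h against 12 h were written before their results.

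Among genes of lists not yet described, the wound keratin Krt6a was higher with Dox in the mean over times (0.71), and so were the cytokine Il7 (0.45) and the protease inhibitor Timp1 (0.50). The epithelial cytokine Tslp (-0.64), the gelatinase Mmp2 (-0.53), the oxidative stress gene Osgin1 (-0.61) and the interferon regulator Irf1 (-0.32, and -0.46 and 0.12 on other probes) were lower. In untreated cultures from 6 h to 72 h, p53 targets (12 higher and 1 lower of 21) and cholesterol synthesis genes (10 and 1 of 16) were higher, at adjusted p = 3.5e-06 and 2.94e-04, with Phlda3 at 2.16, the death receptor Fas at 1.71 (0.78 on its other probe) and the sterol enzyme Nsdhl at 2.07 (0.001 on 1 of its 4 probes). DNA replication genes were higher, 12 and 1 of 26 (5.96e-04, and adjusted p = 0.0707 with an estimated correlation). Antimicrobial genes (1 and 8 of 13, 0.00139), spinous genes (0 and 7 of 11, 0.00437), small proline-rich genes (2 and 7 of 11, 0.0301) and AP-1 genes (1 and 5 of 8, 0.0392) were lower, with the defensin Defb6 at -2.77 and Junb at -1.58, the last 3 calls ending at 0.0708, 0.209 and 0.0708 with an estimated correlation. The AP-1 call ended with median scaling (0.0512) and the small proline-rich call with the Actb covariate (0.0595).

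The remaining lists were not called in the mean over times by camera. Members higher and lower of those measured were 2 and 3 of 8 for the AP-1 family (adjusted p = 0.152), 1 and 3 of 11 for spinous differentiation (0.695), 0 and 6 of 28 for the cornified envelope (0.407), 2 and 2 of 10 for wound keratins (0.862), 1 and 6 of 13 for antimicrobial genes (0.198), 1 and 3 of 10 for chemokines (0.198), 3 and 1 of 18 for epidermal cytokines (0.862), 5 and 3 of 17 for matrix proteases (0.407) and 1 and 4 of 6 for EGF receptor ligands (0.0789). They were 0 and 1 of 12 for interferon response (0.781), 3 and 2 of 16 for cholesterol synthesis (0.407), 2 and 3 of 17 for the lipid barrier (0.866), 3 and 5 of 22 for NRF2 targets (0.862), 3 and 2 of 19 for hypoxia and glycolysis (0.407), 1 and 5 of 21 for p53 targets (0.829), 1 and 0 of 5 for prostaglandins (0.531) and 1 and 5 of 15 for the mesenchymal shift (0.407). Markers of other cells gave 0 and 2 of 6 for fibroblasts (0.407), 1 and 0 of 6 for melanocytes (0.652), 0 and 0 of 4 for leukocytes (0.907), 0 and 0 of 4 for endothelium (0.907), 0 and 1 of 5 for hair follicle (0.94), 0 and 0 of 5 for sebaceous cells (0.658) and 0 and 1 of 7 for muscle (0.658). In the EGF receptor ligand list the 1 member that rose was Errfi1 (0.16), which is neither a ligand nor a receptor. The 1 measured sex gene, Eif2s3y, differed by 0.03 (adjusted p = 0.828).

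Lower Fos signal in cultures meant to induce it was weighed. An exchange of labels at some times and not others is argued against, since Mmp10 and S100a7a both had a higher mean with Dox at 5 of 5 times. The Mmp10 difference did not pass at 6 h, nor the S100a7a difference at 12 h, so the argument is weaker at those times. A general fall of immediate-early transcripts, which would include endogenous Fos, may account for it: 16 measured genes of a list added afterwards had a median of -0.245 in the mean over times, with 10 lower and 0 higher, 11 lower over the list alone. Ier3 (-0.68), Atf3 (-0.61), Egr2 (-0.48) and Junb (-0.43) were among them. The list shares Atf3, Junb and Jun (-0.13, adjusted p = 0.109) with the AP-1 list and was added after the data were seen, so it is not independent evidence. At 6 h its members went both ways, from -0.59 for Zfp36 to 1.40 for Ccn1, so the fall was not general at that time. Exchange of all labels at every time and the position of the probe stay open.

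Slower change of Dox cultures with time was weighed for 72 h. Across genes the 72 h effect correlated with the untreated change from 24 h to 48 h at r = -0.119, and at -0.237 over genes called at 72 h. Lag cannot be told apart from other effects of Dox on this value, which is small and mixes genes that moved either way.

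Of the 203 genes called at 24 h and not with the set block, 78.8% had the sign of the mean 48 h and 72 h effect. The block keeps 1 of 3 Dox arrays there, so calls can end with fewer arrays alone, and whether the array set added calls stays open. Regrouping the 6 replicates at 24 h, 1 of 10 splits gave as many genes as the real 241, with 0 as the highest other by limma; at 72 h it was 1 of 10, with 517 real and 0 the highest other. Those splits are too few to give a share under 0.05. For the mean over times 1 of 100 splits, the real one, gave as many as 1624, the highest other being 338. This argues against a random grouping of replicates as the source of the count. It cannot tell treatment from an array property that falls with it, since the other splits mix the treatments. Untreated 72 h against 12 h gave 0.666 of the count against 6 h, from which the share due to the 6 h arrays cannot be told apart from time.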
